A study of Drosophila melanogaster with 2 samples.

How the data were processed

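The data were ChIP-seq peak lists from whole Drosophila melanogaster embryos (0 to 24 h, mixed sex) of a transgenic line with Bab2 fused to eGFP, precipitated with an anti-GFP antibody, per the labels. Chromatin was fragmented by sonication to 200 to 800 bp, per the labels. There was 1 group with 2 biological replicates, numbered 2 and 3 in the labels and taken from separate biosamples. The labels name a possible control experiment, which was not analysed here.

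For both libraries the authors deposited lists in narrowPeak format on the dm3 and dm6 builds: a relaxed list per replicate, a relaxed list from the reads of both replicates pooled, and an optimal list kept by the irreproducible discovery rate (IDR) procedure, per the README files deposited with the samples. The relaxed lists hold peaks and background as input to that procedure and were called against a control, per the same README files. The aligner, the peak caller, their versions and the read depth per library were not given in the sources used here. The first column used was the signal that the authors deposited per peak, an enrichment whose scaling is not given in the sources used here. It was used only to describe, rank or select peaks within a list. The deposited −log10 (q-value) of each peak ran from 2.65 to 3.90 in the dm6 optimal list, where 84.9% of peaks sat at the ceiling of the list, so it was not used to rank peaks. The other deposited column used was the summit offset in bases from the peak start, from which the summit positions were computed. In both builds, every optimal peak was among the strongest peaks of the pooled list, as many as the optimal list holds, when ranked by signal.

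All coordinates are 1-based on dm6 as the files give them. The reference was the release 6 assembly with the Ensembl 115 gene annotation (FlyBase 6.54), and only the arms 2L, 2R, 3L, 3R, 4 and X were used. These hold 13945 protein-coding genes and 19252 distinct TSS positions over 134 Mb. No coordinates were converted between builds. dm3 peaks were compared with each other and counted only, and for their shifts the end of the last peak of any list stood for the arm length. Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

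A replicate peak counted as shared when a summit of the other replicate lay within 200 bp, among the 4720 strongest peaks of each replicate (the length of the optimal list). Chance shares came from 1000 random circular shifts of all summits along each arm, and two-sided permutation p-values of these have 0.002 as their smallest value. Summits were assigned to classes in the order promoter (within 500 bp of a protein-coding TSS), exon, intron and intergenic. Peak densities carry 95% intervals from 10000 bootstraps of 200 kb blocks. The rank correlation used 1000 bootstraps of peaks and the base composition 2000. Intervals for shares are Wilson for peaks and Clopper-Pearson for genes, at 95%. A count of 0 is given with the limit of 3 over the number of genes. All of these cover counting error only, since PCR duplicates and read depth cannot be judged from peak lists. With 2 replicates in 1 group, no test compares groups. p-values measure departure from shifted positions, other genes or flanking sequence in these lists, not the spread between animals.

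For gene lists, a gene counted when an optimal summit lay within 500 bp of any of its TSSs. Each list was compared with all other protein-coding genes by a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 46 lists and a threshold of 0.05. Each was also set against 10000 random lists matched on the number of TSSs (3 or more as a single class) and on 20 bins of territory length (the stretch nearest to the gene's own TSSs). Peaks assigned by nearest TSS were summarised as the median per list against 10000 lists matched on 50 bins of territory length. The lists covered the bab genes, leg patterning, pigmentation, gonad, sex determination, segmentation and Hox genes, ecdysone response, BTB factors, neural, glial, muscle, tracheal, epidermal, gut, blood, fat body and eye genes, signalling pathways, chromatin and insulator proteins, apoptosis, cell cycle, housekeeping machineries, receptor, seminal, chorion, Osiris and cuticle families, and heat shock genes. Of 1165 names and pattern matches, 25 were matched through an older symbol and 5 were not matched. After the first results had been seen, the spelling of several names was brought to that of the annotation (Dl to Delta, for example), and a pigmentation alias that matched another gene (tan, read as tant) was dropped. These corrections moved no list across the threshold in the promoter test, and moved the BTB and BMP lists out of those that passed by the mean number of assigned peaks.

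Motifs were searched on both strands within 50 bp of the summit (101 bp windows) and in a window of equal length centred 500 bp away on a randomly chosen side. The 30 motifs were tested by the exact McNemar test with Benjamini-Hochberg adjustment. Motif shares of promoter and other peaks were compared by Fisher's exact test. Genes named in the text were those nearest to the 25 strongest peaks, the 5 with the most assigned peaks, up to 4 members per list with the highest signal at a promoter summit (for a list with none, the 2 with the strongest assigned peaks), and bab1 and bab2 always. The tests, the gene lists, the motifs, this naming rule and the alternatives listed next were fixed before the data were examined, apart from the spelling corrections above. Not among the tests fixed in advance were the side of the TSS on which promoter summits lay and the comparison of motif shares between promoter and other peaks.

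The alternatives were other summit distances, 50% reciprocal overlap, other sets of peaks and the dm3 lists for overlap, the 2360 peaks of higher signal, each replicate's own strongest 4720 peaks in place of the optimal list (leaving out the other replicate), TSS windows of 250 and 1000 bp, motif windows of 100 bp each side, flanks 1000 bp away, peaks farther than 500 bp from a TSS, assigned genes as background, and assignment within 10 kb. Added after the data had been seen were shifts and lengths restricted to 100 kb windows that hold peaks (93.2% of the arms), the mean in place of the median for assigned peaks, and motifs in promoter peaks only. The planned use of the strongest pooled peaks in place of the optimal list gave the same peaks and was therefore no separate alternative.

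The tests were checked on simulated data. With 4720 random summits, 6 of 100 runs passed the promoter test, 4 of 100 the overlap test and 5 of 100 gave an X to autosome interval without 1. With 10% of summits placed at TSSs or shared between lists, all 100 runs passed, and 9.88% and 10.0% were recovered. Of lists of 50 genes, 0 of 20 without an effect, 9 of 10 with a doubled share and 10 of 10 with a tripled share passed the promoter test. For assigned peaks 0 of 30 lists passed without an added peak per gene and 10 of 10 with it. The added peak lay at a TSS of nearly every member, so this last result was largely fixed in advance. Random summits were drawn uniformly, which need not hold for real peaks. Many of the real lists were smaller than 50 genes, and power for those was not measured. Over 150 motif tests at random summits 2 passed, and a motif placed at 5% of summits was called in 5 of 5 runs with 5.04% recovered.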

Results

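Chromatin bound by Bab2 (bric-à-brac 2) was profiled by ChIP-seq in whole Drosophila melanogaster embryos of mixed sex, collected at 0 to 24 h. Bab2 is a BTB-domain transcription factor known for its roles in leg segmentation, ovary terminal filament formation and abdominal pigmentation. The flies carried a transgene for Bab2 with eGFP at its C-terminus, and chromatin was precipitated with an antibody against GFP. There was 1 group with 2 libraries, biological replicates 2 and 3, each from its own biosample. The deposited peak lists held 27372 peaks for replicate 2, 25804 for replicate 3, 24109 for the reads of both replicates pooled, and 4720 in the optimal list that passed the irreproducible discovery rate procedure (dm6 build). The number of reads behind these lists was not given in the sources used here. Signal in the optimal list ran from 76.1 to 2524 (median 128, the authors' value per peak from pooled reads), and peaks had a median width of 424 bp. Each peak has a single signal value and therefore no standard deviation. Intervals on shares of peaks or genes cover counting error only.

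The first question was how far the replicates marked the same sites. Of the 4720 strongest peaks of replicate 2, 3777 (80.0%) had one of the 4720 strongest replicate 3 summits within 200 bp. Shifted copies of the replicate 2 peaks gave 1.38% (central 95% of shifts 1.04% to 1.76%; permutation p = 0.002, the smallest that 1000 shifts can give). In the opposite direction the share was 79.5%. Of the 4720 optimal peaks, 4707 (99.7%) were found in the full replicate 2 list and 4714 (99.9%) in the full replicate 3 list, which was largely fixed in advance because the optimal list was selected for reproducibility between these replicates. Over the 4701 optimal peaks found in both, the signals of the replicates were correlated across peaks (Spearman's rho 0.759, 95% bootstrap interval 0.743 to 0.774), with peaks not being independent replicates. Without peaks near a TSS the rho was 0.729 (2522 peaks).

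The strongest Bab2 peaks lay close to gene starts and ranked near the top in both replicates. The strongest (2L, 480846 to 481317, dm6, signal 2524) lay in an intron of ush, a GATA cofactor gene, 1369 bp upstream of the nearest TSS, that of cbt (FBgn0043364), which encodes a zinc finger transcription factor. The next were CG14100 (FBgn0036889; 3L, 19590405 to 19590828, signal 2503, 95 bp upstream of the TSS) and Ugalt (FBgn0024994; X, 2703667 to 2704099, signal 2133, 36 bp upstream), which encodes a UDP-galactose transporter. They were followed by px (FBgn0003175; 2R, 22514087 to 22514536, signal 1865, intron), a wing vein gene, and CG11050 (FBgn0031836; 2L, 6612488 to 6612917, signal 1815, intron). Chromatin regulators were among the 10 strongest. The Polycomb group gene ph-p (FBgn0004861; X, 2137150 to 2137593, intron) had a signal of 1578, and Chro (FBgn0044324; 3L, 22878687 to 22879122, 5' UTR), which encodes a chromodomain protein of interbands and insulators, had 1520. Lk6 (kinase), PNPase (polynucleotide phosphorylase) and mRpL41 (mitochondrial ribosomal protein) had signals of 1667, 1642 and 1519. The others of the 25 strongest had Tcs5, CG1888, CenG1A, Shc, Art3, CG9147, CG32772, CG9663, CG8320, gish, CG13323, Pal1, larp, GstE13 and CG31145 as their nearest gene, with signals from 1179 to 1513. Of the 25 summits, 19 lay within 500 bp of a TSS and 11 lay in introns. All 25 were found in both replicates, at rank 26 or better in replicate 2 and 28 or better in replicate 3. These high ranks were largely fixed in advance, because the 25 were chosen by signal from the pooled reads of the same replicates.

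The next question was where in the genome the peaks lay. Bab2 summits were concentrated at promoters relative to shifted positions along the arms. A mock precipitation was not analysed here. Binding by Bab2 at promoters therefore cannot be told apart from a bias of ChIP towards highly transcribed loci. Of 4720 optimal summits, 2190 (46.4%, Wilson 95% interval 45.0% to 47.8%) lay within 500 bp of a protein-coding TSS, against 11.5% of shifted summits (central 95% 10.3% to 12.7%), a 4.04-fold excess. Exons outside promoters held 83 summits (1.76%, chance 19.3%), introns 1703 (36.1%, chance 39.3%) and intergenic sequence 744 (15.8%, chance 29.98%). The permutation p was 0.002 for promoters, exons and intergenic sequence, the smallest that 1000 shifts can give, and 0.00599 for introns. Promoters were assigned first, so their excess lowers the share left for every other class. Of the 2530 summits outside promoters, 1703 lay in introns. The ratio of observed to chance share was 0.918 for introns, 0.526 for intergenic sequence and 0.0913 for exons. Among summits outside promoters, introns therefore held a larger share than among shifted ones, and the lower intron share does not show avoidance. That comparison was not tested. Promoter summits mostly lay just upstream of the start site: 1798 lay upstream and 388 downstream (82.3% upstream, leaving out summits at the TSS base itself), against 45.1% of shifted promoter summits (permutation p = 0.01, the smallest that 200 shifts can give), at a median of -93 bp from the nearest TSS (quartiles -182 and -27 bp). The lower intron share was not seen with a TSS window of 250 bp, where introns held 40.7% of summits against 40.8% by chance (permutation p = 0.907).

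**Figure D1:**
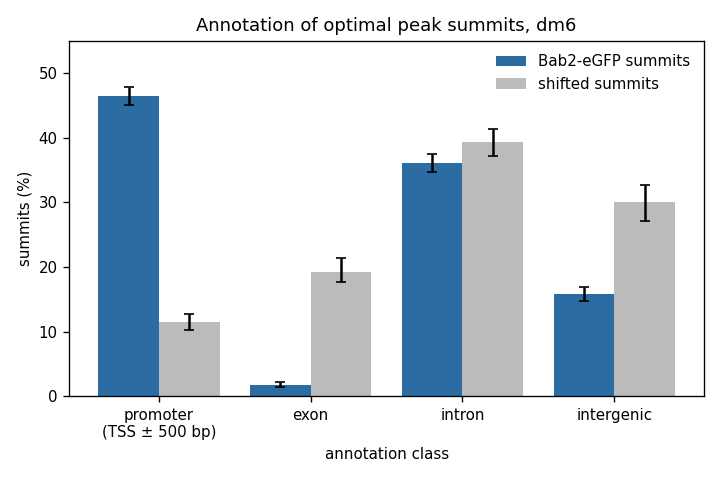
Share of optimal peak summits (y axis, percent) in each annotation class (x axis, in order of priority from the left), for the 4720 Bab2-eGFP summits (blue, Wilson 95% intervals) and for 1000 circular shifts of them (grey, mean and central 95%). Promoters held 46.4% of summits against 11.5% by chance, and exons 1.76% against 19.3%.

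Peak density was similar on the large chromosome arms and lower on chromosome 4. The arms 2L, 2R, 3L, 3R and X had 37.4, 33.8, 34.4, 34.9 and 37.5 peaks per Mb, with 95% block bootstrap intervals that together spanned 29.2 to 42.3. Chromosome 4, a small and largely heterochromatic chromosome, had 17 peaks, or 12.6 per Mb (4.63 to 20.8). The X carried 1.08 times as many peaks per Mb as the autosomes (0.929 to 1.24), an interval that includes 1. With the dm3 list the ratio was 0.967 (0.842 to 1.10).

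Genes with a Bab2 summit at a TSS were then compared among 46 gene lists. Across 13945 protein-coding genes, 2797 (20.1%) had an optimal summit within 500 bp of a TSS. The lists that stood above other genes were of translation and of chromatin genes. Cytoplasmic ribosomal protein genes had one at 53 of 86 (61.6%, Clopper-Pearson 95% interval 50.5% to 71.9%). Among them were RpL32 (3R, 30046167 to 30046519, signal 619.5, 185 bp upstream of the TSS), RpS27 (3R, 25247392 to 25247644, signal 540.3, 11 bp upstream), RpL7 (2L, 10200909 to 10201146, signal 497, 5' UTR) and RpL14 (3L, 8600825 to 8601067, signal 438, 69 bp upstream). Mitochondrial ribosomal protein genes had one at 27 of 73 (37.0%, 26.0% to 49.1%), with mRpL41 (signal 1519), mRpS23 (1475), mRpS10 (1327) and mRpL23 (997) the highest. The mRpS23 peak (2L, 13835271 to 13835662) was also the one nearest to CenG1A, and the mRpS10 peak (3R, 15229337 to 15229725) the one nearest to Art3, since these genes have neighbouring start sites. Such sharing went beyond these genes. By nearest TSS only 12 of the 73 had an assigned peak, so many of the 27 had a summit that was assigned to another gene. The mean of assigned peaks, a measure chosen after the data had been seen, showed no excess (0.164, matched mean 0.187, adjusted permutation p = 0.960).

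Histone variant and heterochromatin genes had a promoter summit at 7 of 11 (63.6%, 30.8% to 89.1%). They included His2Av (3R, 26866621 to 26866817, signal 337, in an intron of ball), His3.3B (X, 9155067 to 9155490, signal 157), Su(var)3-7 (3R, 13263972 to 13264395, signal 118) and the HP1a gene (FBgn0003607; 2L, 8211111 to 8211534, signal 104). Insulator and architectural protein genes had one at 8 of 14 (57.1%, 28.9% to 82.3%), with Chro (signal 1520), Cp190 (3R, 15275223 to 15275387, signal 377), BEAF-32 (2R, 14770200 to 14770623, signal 177) and Dref (2L, 9967045 to 9967468, signal 173). Polycomb and trithorax group genes had one at 11 of 21 (52.4%, 29.8% to 74.3%), with ph-p (signal 1578), Trl (3L, 14757099 to 14757314, signal 358, 5' UTR), which encodes the GAGA factor, brm (3L, 15982864 to 15983103, signal 289), the ATPase of the SWI/SNF remodeler, and the histone methyltransferase gene E(z) (3L, 10638078 to 10638188, signal 250.2, 5' UTR).

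These 5 lists were higher than other genes by Fisher's exact test (two-sided, Benjamini-Hochberg over the 46 lists). Adjusted p was 1.73e-15 for cytoplasmic ribosomal proteins, 0.00666 for mitochondrial ribosomal proteins and for the Polycomb and trithorax group, 0.0115 for histone variants and 0.0124 for insulator proteins. Against 10000 random lists matched on TSS number and territory length, all but the insulator list passed (adjusted p 0.0661 for that list). Of the lists called in both directions, 9 of 10 passed against matched lists, but only 7 of 9 without replicate 3, 6 of 9 with a TSS window of 250 bp and 3 of 6 with the 2360 peaks of higher signal. The 53 cytoplasmic ribosomal protein genes exceeded the matched mean of 24.5 and maximum of 39. Some calls ended by the same exact test: without replicate 3, histone variants had 36.4% (adjusted p = 0.43) and mitochondrial ribosomal proteins 31.5% (adjusted p = 0.0777), without replicate 2, insulator proteins had 50% (adjusted p = 0.0554), and with the 2360 peaks of higher signal, the Polycomb and trithorax group had 28.6% (adjusted p = 0.151) and histone variants 18.2% (adjusted p = 0.64). A background of only genes with an assigned peak asks where the peaks of a gene lay, not how many genes had one. A gene whose territory hardly reaches past 500 bp could have an assigned peak only at its promoter. This background is therefore no separate evidence for one list over another. With it, only the ribosomal protein lists stayed higher, and none of the chromatin lists passed. Their shares stayed above the 65.3% of background genes, with few genes left: 10 of 12 for the Polycomb and trithorax group (exact test, adjusted p = 0.331), 6 of 6 for insulator proteins (adjusted p = 0.154) and 3 of 4 for histone variants (adjusted p = 1.0).

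The lists that stood below other genes were families of cuticle, chemoreceptor and seminal fluid genes and epidermal genes. None of the 95 cuticle genes of the Cpr and Twdl families had a promoter summit, which allows a share of up to 3.16%. The same held for 0 of 60 gustatory receptor genes (up to 5%), 0 of 59 odorant receptor genes (up to 5.08%) and 0 of 25 genes of epidermis and cuticle formation (up to 12%). Accessory gland and seminal protein genes had 1 of 47 (2.13%), Sfp26Ad, whose peak (2L, 5943588 to 5943694, signal 187) lay in the 5' UTR of Gpdh1. The strongest peaks assigned to members of these lists without a promoter summit were those of Cpr76Ba (signal 298), Cpr92A (248), Gr93a (231), Gr89a (193), Or98a (83.9), the epidermal regulator grh (288) and the actin-bundling gene sn (202). All 5 lists were lower than other genes by Fisher's exact test, with adjusted p of 2.36e-08 for cuticle families, 3.43e-05 for gustatory receptors, 4.34e-05 for odorant receptors, 0.00648 for accessory gland genes and 0.0242 for epidermis. All 5 also passed against matched lists (adjusted p from 0.00307 to 0.0218). With the 2360 peaks of higher signal, epidermis (adjusted p = 0.357, exact test) and accessory gland genes (adjusted p = 0.176) did not pass, nor did epidermis with a TSS window of 250 bp (adjusted p = 0.0878). With assigned genes as background, gustatory receptors and epidermis did not pass (exact test, adjusted p = 0.0795 for both), odorant receptors and accessory gland genes had too few genes to be tested, and only the cuticle families stayed lower (0 of 4 genes, adjusted p = 0.0404). The other 12 of the 13 lists lower by that background were not called among all genes, and no matched lists were drawn for it.

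**Figure D2:**
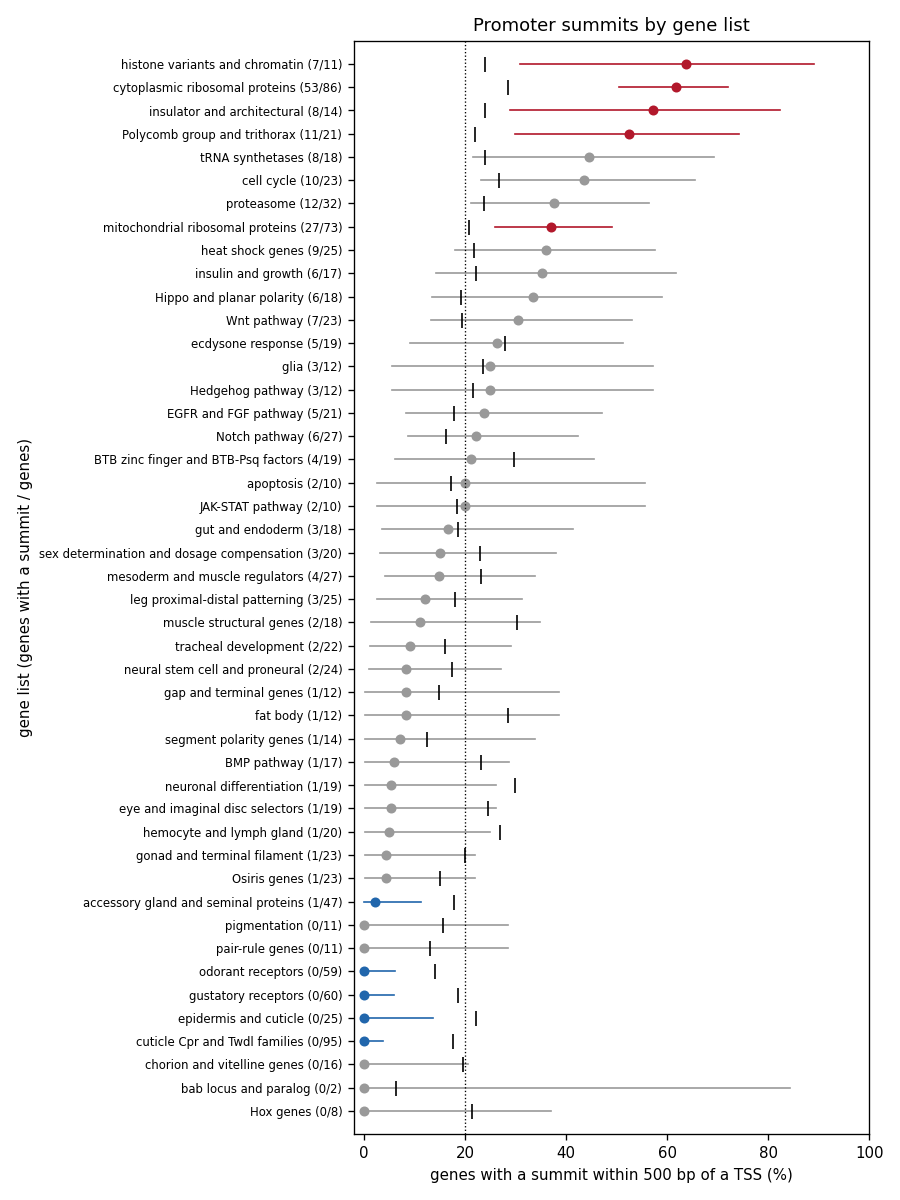
Percent of genes with a summit within 500 bp of a TSS (x axis) for each of the 46 gene lists (y axis), with Clopper-Pearson 95% intervals; red lists were higher and blue lists lower than other genes, grey lists did not pass the test, black ticks are the mean of matched random lists and the dotted line is the share among all genes (20.1%). Cytoplasmic ribosomal proteins stood at 61.6% and the cuticle families at 0.

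Of the other 36 lists, none passed the Fisher test after adjustment (smallest adjusted p 0.0621), and 3 had an unadjusted p under 0.05: tRNA synthetases (8 of 18, SerRS signal 385), cell cycle genes (10 of 23, with Dp 480.5, aurA 233, dup 191 and Cdk1 145.5) and the proteasome (12 of 32, Rpn5 signal 345). Cell cycle genes passed the exact test without replicate 3 (10 of 23, adjusted p = 0.0445) and with a TSS window of 1000 bp (47.8%, adjusted p = 0.0426), and Hippo and planar polarity did so with that window (55.6%, adjusted p = 0.0166). Heat shock genes had a promoter summit at 9 of 25, with Hsp27 (signal 383), Hsp26 (246), Hsp83 (215) and Hsc70-5 (191) the highest. Counts in signalling pathways were 7 of 23 for Wnt, 6 of 27 for Notch, 6 of 17 for insulin and growth, 6 of 18 for Hippo and planar polarity, 5 of 21 for EGFR and FGF, 3 of 12 for Hedgehog, 2 of 10 for JAK-STAT, 1 of 17 for BMP and 5 of 19 for the ecdysone response. Their strongest promoter peaks were at sgg (signal 561), the GSK3 gene of the Wnt pathway, spi (484), which encodes the EGFR ligand Spitz, E23 (382), E(spl)m3-HLH (292), shn (256), hpo (234.5), InR (231), ttv (171) and Stat92E (142). The apoptosis list had 2 of 10, hid (signal 242) and Drice (89.0). Differences from other genes changed direction in some of these lists: without replicate 3, Notch had 18.5% (other genes 19.6%), and without replicate 2, JAK-STAT and apoptosis each had 3 of 10 (other genes 20.1%). JAK-STAT had 1 of 10 without replicate 3.

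Among tissue lists, 3 of 12 glial genes (moody, Gli and nrv2), 1 of 19 neuronal differentiation genes (elav, signal 493), 2 of 24 neural stem cell and proneural genes (brat and vnd) and 2 of 18 muscle structural genes (Msp300, signal 466.5, and sls, 391) had a promoter summit. Counts were 4 of 27 for mesoderm and muscle regulators (rols, htl, tin and sd), 3 of 18 for gut and endoderm (bowl, fkh and emc), 2 of 22 for tracheal development (sima and trh), 1 of 20 for hemocyte and lymph gland (ush), 1 of 12 for fat body (Adh, signal 241), 1 of 19 for eye and disc selectors (sd) and 1 of 23 for the Osiris genes (Osi24). Among axis and segment genes, counts were 1 of 12 gap and terminal genes (bcd, signal 210.0), 1 of 14 segment polarity genes (nkd, 180.2), 0 of 11 pair-rule genes (up to 27.3%) and 0 of 8 Hox genes (up to 37.5%). Without replicate 3, segment polarity had 3 of 14 (21.4%) and gut and endoderm 4 of 18 (22.2%), above the 19.6% of other genes, while neural stem cell genes had 1 of 24 and tracheal genes 1 of 22. Without replicate 2, neuronal differentiation and eye and disc selectors each had 2 of 19 and tracheal genes 1 of 22. The strongest peaks assigned to Hox and pair-rule genes were those of Antp (signal 162, intron), Ubx (146, intron), slp2 (550.5, intergenic) and slp1 (134, intergenic). BTB zinc finger and related factors, a list that includes bab1 and bab2, had 4 of 19 (Cp190, Trl, lola and lolal), and sex determination and dosage compensation had 3 of 20 (gro, signal 566, Sxl, 167, and emc, 80.7).

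Among the lists tied to the known roles of Bab2, leg proximal-distal patterning had promoter summits at 3 of 25: bowl (2L, 3771326 to 3771521, signal 374), lin (2R, 8913883 to 8914306, signal 118.5) and Sp1 (X, 9729557 to 9729980, signal 76.3, 5' UTR). Gonad and terminal filament had 1 of 23, Sox100B (3R, 31064577 to 31065000, signal 108), but 3 of 23 (13.0%) without replicate 2 and 2 of 23 (8.70%) without replicate 3. Pigmentation had 0 of 11 (up to 27.3%), with assigned peaks at bi (X, 4446090 to 4446513, signal 160.0, intron) and at y (X, 362139 to 362562, signal 111, in an intron of CG32816, 5842 bp downstream of the TSS). Chorion and vitelline genes had 0 of 16 (up to 18.8%). None of these 4 lists passed the exact test against other genes (adjusted p from 0.180 to 0.669). Pigmentation and chorion genes could not have passed as lower, since a count of 0 gave them an unadjusted p of 0.136 and 0.0547 in that test. Leg patterning, gonad and pigmentation genes were among the 13 of 42 lists lower with assigned genes as background, which is no separate evidence, since that background takes in genes through peaks away from promoters.

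All peaks, at promoters and elsewhere, were counted by assigning each summit to the nearest TSS. This gave 3140 genes with at least 1 peak, of which 99 had 5 or more and 2051 (65.3%) had a promoter summit. The genes with the most were shn (FBgn0003396; 2R, 11159086 to 11217394), a zinc finger effector of BMP signalling, with 15 peaks where its territory would hold 1.68 at the mean density, CG43245 (3L) with 12, CHES-1-like (X), a forkhead gene, with 12, the growth regulator Myc (X) with 11 and the Tousled-like kinase gene Tlk (X) with 10. By the median per list, only cytoplasmic ribosomal proteins passed against lists matched on territory length (median 1, mean 0.570 ± 0.564, SD over 86 genes; adjusted permutation p = 0.0092). Of the 46 ribosomal protein genes with an assigned peak, 45 (97.8%) had a promoter summit, so this largely restated the promoter result. No list did so with the 2360 peaks of higher signal. A lower list could not be detected by the median, because matched lists often had a median of 0. By the mean, chosen after the data had been seen, 5 lists were higher and 4 lower. Ecdysone response genes had 50 peaks over 19 genes (mean 2.63 ± 3.09, matched mean 0.915, adjusted permutation p = 0.00767), and EGFR and FGF pathway genes had 49 over 21 (2.33 ± 2.80, matched 0.751, adjusted p = 0.00552). Insulin and growth had a mean of 1.35 ± 2.76 with a median of 0 (adjusted permutation p = 0.0225), and the Polycomb and trithorax group 1.24 ± 1.58 with a median of 1 (adjusted p = 0.00552). The 4 lower lists were gustatory receptors (mean 0.0667), cuticle families (0.0421), odorant receptors (0.0169) and accessory gland genes (0 peaks).

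Because the line carried a tagged copy of bab2, the bab locus was examined by itself. Of the 7 peaks assigned to it, 2 were nearest to bab1 and 5 to bab2, and none lay at a promoter. Without replicate 3, that is among the strongest peaks of replicate 2 alone, 1 of the 2 bab genes had a promoter summit (50%). The strongest (3L, 1139345 to 1139768, signal 269, rank 680) was intergenic, beyond the 3' end of bab2 (1140429 to 1177276, minus strand). Another pair lay in an intron of bab2 at 1166226 to 1166649 (signal 216) and 1166889 to 1167312 (signal 228), and weaker intronic peaks lay at 1151536 to 1151959 (105.5) and 1152684 to 1153107 (98.2). The bab1 peaks lay in introns at 1086196 to 1086619 (84.9) and 1096940 to 1097363 (110.5). The 7 peaks did not exceed chance (mean 3.74, central 95% of shifts 0 to 12, permutation p = 0.39). A transgene copy can raise reads over the tagged gene, and peak lists cannot tell this apart from binding within bab2.

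**Figure D3:**
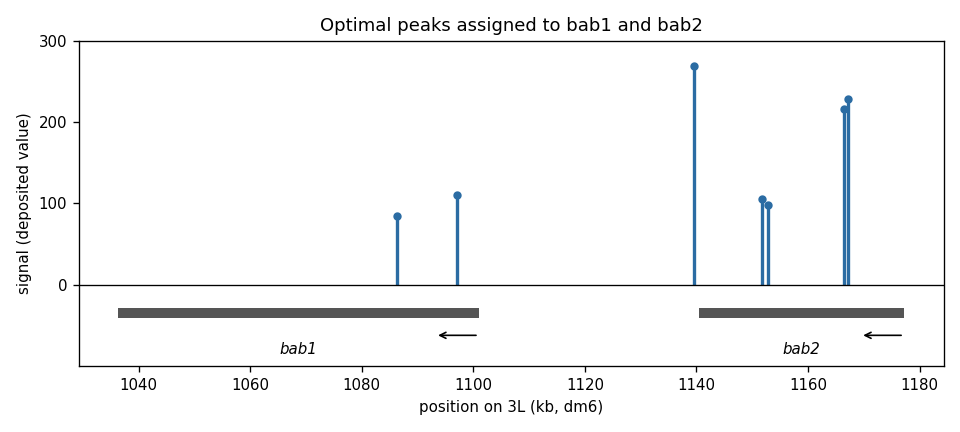
Optimal peaks assigned to bab1 and bab2 along arm 3L (x axis, kb, dm6), each drawn at its summit with the deposited signal as its height (y axis), above the extents of both genes (grey bars, arrows in the direction of transcription). The highest of the 7 peaks, at 269, stands beyond the 3' end of bab2.

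Bab proteins carry a DNA-binding domain described to bind A/T-rich sequence, so base composition was measured at summits. Windows within 50 bp of summits had 64.2% ± 8.65 A+T (SD over 4720 peaks), against 56.5% ± 10.3 in windows 500 bp away and 57.8% over the 6 arms. The difference was 7.75 percentage points (95% bootstrap interval 7.35 to 8.15), and 71.6% of peaks had the higher value at the summit. It was 9.12 points (8.50 to 9.75) in the 2190 promoter peaks, with 63.3% at summits and 54.2% in flanks. In the 2530 peaks farther than 500 bp from a TSS it was 6.64 (6.14 to 7.14), with 65.0% and 58.4%. The larger excess at promoters thus went with flanks poorer in A+T, not with summits richer in it.

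**Figure D4:**
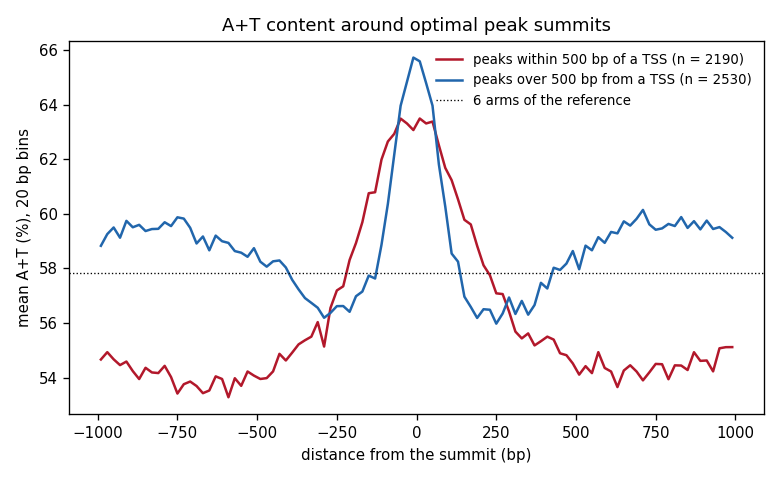
Mean A+T content (y axis, percent, 20 bp bins) by distance from the summit (x axis, bp) for the 2190 peaks within 500 bp of a TSS (red) and the 2530 peaks farther away (blue), with the level of the 6 arms dotted. The highest bin was 63.5% for promoter peaks and 65.7% for the others.

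Of 30 motifs tested, 12 were more frequent at summits than in the flanks of the same peaks and 5 less frequent (exact McNemar test, two-sided, Benjamini-Hochberg over 30 motifs). The A/T repeat AATAAT was found at 19.8% of summits and 12.5% of flanks (exact test, adjusted p = 5.58e-20), the TATA box word at 17.6% and 11.1% (adjusted p = 3.77e-18), TAATAA at 15.5% and 10.7%, TATATA at 7.61% and 5.08%, homopolymer A at 11.0% and 8.75% and the homeodomain word TAATTA at 7.44% and 6.10%. Among factor motifs, the forkhead word TGTTTAC was at 4.45% of summits and 1.93% of flanks (exact test, adjusted p = 1.64e-11) and the word listed for Su(Hw), TGCATA, at 8.94% and 6.02% (adjusted p = 2.91e-07). Among motifs of housekeeping promoters, DREF (TATCGATA) was at 1.99% and 0.254% (exact test, adjusted p = 9.40e-17), Ohler 7 at 3.54% and 1.23%, the BEAF word CGATA at 16.9% and 12.1% and M1BP (GGTCACAC) at 0.932% and 0.191%. The M1BP ratio of 4.89 was 2.88 without replicate 2 and 2.71 without replicate 3, with flanks at 0.360% in both cases. Less frequent at summits were TTK (8.96% and 12.3%), GAGA (4.0% and 5.40%), CACA repeats (1.57% and 3.37%), Runt (1.40% and 2.86%) and the DPE-like word (1.44% and 2.18%). Some calls depended on the flanks: with flanks 1000 bp away, GAGA (4.0% and 4.32%, exact test, adjusted p = 0.59), CACA repeats (1.57% and 2.08%, adjusted p = 0.12) and TAATTA (7.44% and 6.40%, adjusted p = 0.0926) did not pass.

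The housekeeping motifs were more frequent at promoter summits than at the others. Since they are promoter motifs, this could follow from position near a TSS alone. Promoters without a summit were not searched, so neither this difference nor the excess over flanks can be credited to Bab2. DREF was found at 4.16% of promoter summits and 0.119% of the others (Fisher's exact test, adjusted p = 5.44e-26), BEAF at 24.3% and 10.6% (adjusted p = 1.23e-34), Ohler 7 at 6.16% and 1.26% (adjusted p = 1.48e-19) and M1BP at 1.78% and 0.198% (adjusted p = 4.02e-08). Su(Hw) went the other way, with 7.21% and 10.4% (exact test, adjusted p = 5.18e-04), whereas the repeat AATAAT (20.6% and 19.1%, adjusted p = 0.295) and the forkhead word (3.74% and 5.06%, adjusted p = 0.0773) did not pass. In the peaks farther than 500 bp from a TSS, 5 motifs were more frequent at summits than in flanks (AATAAT, TAATAA, the TATA box word, Su(Hw) and forkhead). Without replicate 3, the lower shares of GAGA and of the DPE-like word did not pass (exact test, adjusted p = 0.36 for both). Without replicate 2, the E-box words CAGCTG (adjusted p = 0.00317, exact test) and CACGTG (adjusted p = 0.0372) were also less frequent at summits than in flanks.

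The same lists were deposited for the older dm3 build, on which the optimal list held 4477 peaks. The dm6 list was 1.05 times as long. The pooled list was 1.11 times, the replicate 2 list 1.11 times and the replicate 3 list 1.12 times as long on dm6 as on dm3.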

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

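The comparison in this part was chosen only after the lists had been seen. The 19389 pooled peaks below the signal of the optimal list, which no comparison above uses, were looked up in the full replicate lists because a signal in unused data would call for a closer look. Of these, 9516 (49.1%) had a summit within 200 bp in both replicate lists, against 3.68% when these pooled peaks were shifted (central 95% 3.36% to 4.07%; permutation p = 0.002, the smallest that 1000 shifts can give). The pooled list was called from the reads of the same 2 replicates, so the lists are not independent, and no explanation of the excess was tested.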

How the results depend on the processing

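The alternatives named here as added were chosen only after the data had been seen. Among the values of the main results under alternatives, 75 kept their direction and side of the threshold or their size, 11 moved, 1 was weaker and 1 reversed. The kept ones include counts of 0 lower lists by the median of assigned peaks, which could not show a lower list. Among those of single lists and motifs, 145 were kept, 28 were weaker and 4 reversed. Rank correlation was 0.729 over peaks farther than 500 bp from a TSS. The intron share was 40.7% with a TSS window of 250 bp, no longer below chance. With the dm3 list the X to autosome ratio was 0.967, on the other side of 1, with an interval that includes 1 as on dm6. The 2360 peaks of higher signal gave 3 higher and 3 lower lists by promoter summits and 0 higher by assigned peaks, with fewer genes having a peak. Assigned genes as background gave 2 higher and 13 lower, with 42 lists tested and 65.3% of background genes having a promoter summit. The mean in place of the median (added) gave 5 higher and 4 lower lists by assigned peaks. Peaks farther than 500 bp from a TSS gave 5 higher and 3 lower motifs. There the DREF share at summits was 0.119% (flanks 0.237%), BEAF 10.6% (11.3%) and TTK 9.96% (9.49%), each turned against the direction over all peaks and not past the threshold. With windows of 100 bp each side, GAGA was at 10.2% of summits and 10.04% of flanks, also turned. Leaving out 1 replicate gave 3 to 7 lower motifs (3 without replicate 3, 7 without replicate 2). Except where the alternative's own construction is named, the cause was not tested. The overlap of replicates ran from 52.4% (all peaks) to 83.3%, above chance under each alternative, apart from the 99.6% of optimal peaks in both full lists, which follows largely from how that list was selected. The promoter share ran from 37.7% to 55.6%. The strongest peaks of the pooled list were the optimal list itself, so that alternative gave no separate value. No paired analysis was possible because there was a single group. Read depth is unknown, so what it limits could not be measured.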

Other observations

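The tests in this part of groups by signal, short words and tRNA genes were chosen only after the results they bear on had been seen. The matched lists and the peaks farther than 500 bp from a TSS had been planned, but their use against the number and spacing of TSSs and against promoter sequence was chosen after those results had been seen. Peaks of the highest signal differed from the weakest optimal peaks in where they lay and which motifs they held. The share within 500 bp of a TSS was 55.8% in the highest of 5 groups of 944 peaks by signal (223 to 2524) and 40.1% in the lowest (76.1 to 90.9; Fisher's exact test, adjusted p = 8.11e-11 over 7 features). The housekeeping motifs tested here, which left out M1BP, went the other way, with DREF at 0.847% and 2.54% (exact test, adjusted p = 0.0114), BEAF at 11.8% and 18.0% (adjusted p = 5.92e-04) and Ohler 7 at 2.01% and 4.87% (adjusted p = 0.00208). TAATAA was at 18.6% and 14.3% (exact test, adjusted p = 0.0182), while AATAAT (22.1% and 19.4%, adjusted p = 0.182) and forkhead (4.34% and 5.40%, adjusted p = 0.336) did not pass.

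All 2080 words of 6 bases were counted at summits and flanks. At promoters 391 were higher at summits and 670 lower, and in the other peaks 395 and 621, with 486 and 471 of the lower words holding 4 or more G or C bases. Among the higher words with at least 2 G or C bases, CGATAG (11.1% of promoter summits and 2.56% of flanks, exact McNemar test, adjusted p = 5.56e-28), TATCGA (12.9% and 3.70%) and ACACTG (10.5% and 3.56%) led at promoters, and AGTGTA (8.70% and 3.75%, adjusted p = 3.89e-11), AGCTTA (7.00% and 3.24%) and AAGCTA (7.19% and 3.48%) led in peaks farther than 500 bp from a TSS. ACACTG was also higher in the latter (7.47% and 3.87%, exact test, adjusted p = 5.41e-07). Genes of tRNAs, which are transcribed by RNA polymerase III, had an optimal summit at 17 of 290 (5.86%, Clopper-Pearson 95% interval 3.45% to 9.22%), where protein-coding genes had 20.1%. In the pooled list these shares were 37.6% (32.0% to 43.4%) and 47.0%. A protein-coding gene could count through any of its TSSs, so the shares are not fully alike. No p-value was computed for them, and read mapping at tRNA genes cannot be judged from peak lists.

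Promoter peaks at 53 of 86 cytoplasmic ribosomal protein genes are a pattern that could come from technical sources. Other housekeeping lists also lay above the 20.1% of all genes: tRNA synthetases at 44.4% (8 of 18, 21.5% to 69.2%), the proteasome at 37.5% (12 of 32, 21.1% to 56.3%) and mitochondrial ribosomal proteins at 37.0%. The tRNA synthetases and the proteasome, with fewer genes, did not pass. Mitochondrial ribosomal proteins lost their call without replicate 3, at 31.5% against 19.6% of all genes (exact test, adjusted p = 0.0777). No test compared these lists with each other, so whether they carry the pattern equally was not decided. For the cytoplasmic ribosomal protein genes, the number and spacing of TSSs is argued against, since none of 10000 lists matched on both reached 53 (highest 39). A bias of ChIP towards highly transcribed loci stays open: the median signal of the ribosomal protein promoter peaks was 164, inside the range of random sets of other genes with a promoter peak (119 to 181), which decides neither way, since a value above that range would have spoken for the bias and one below it against. It cannot be told apart from binding at these promoters here, because expression and a mock precipitation were not analysed here. No biological explanation was tested, since the design has a single group.

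A/T-rich words at summits are the other pattern weighed. Base composition may account for the excess of these words over flanks, but for 5 of the 6 words it predicted a larger excess than was seen. The bases of each window were shuffled for this. Of the 6 A/T words, 0 had a higher observed-to-shuffled ratio at summits than in flanks, and 5 had a lower one. For those 5, the ratio at summits was 0.644 (TAATTA) to 0.904 (AATAAT) times that in flanks. For peaks farther than 500 bp from a protein-coding TSS, promoter sequence as the source of the A+T excess is argued against by its value of 6.64 percentage points (6.14 to 7.14) there. Starts of other genes were not considered. The value does not speak to the 2190 promoter peaks, where the excess was 9.12 points and promoter sequence stays open. What sets the composition stays open, and no biological explanation was tested.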
